A study of Mus musculus with 8 samples.

How the data were processed

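RNA-seq libraries from the hippocampus of 9-week-old mice were compared between 2 genotypes, wild type (WT) and hemizygous carriers of the T29-1 transgene, in which the Camk2a promoter drives Cre recombinase. There were 4 libraries per genotype, named here by genotype and replicate number as in the labels. Per the labels' protocols, total RNA was purified with Isogen II, poly(A) RNA was isolated from 500 ng of it, stranded libraries were made with a directional kit, and all libraries were pooled on 1 lane for paired-end reads of 150 bp. Per the submitters' processing notes, STAR 2.6.1d, featureCounts and edgeR 3.11 were used with the mouse genome build GRCm38. The annotation release, the strand setting of the counting, the rule for reads that map to several places and the version of featureCounts are not given in the sources used here.

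The authors deposited a table of read counts per gene name, with 46078 rows and whole-number, unscaled values for the 8 libraries. Every count column matched a sample by its name. Of its 45806 distinct names, 216 had more than 1 row, and these rows were kept apart (114 of the tested rows have such a name). A further 25 names had been turned into dates, of which 23 were tested under those names. The authors also deposited a table of their comparison with a log2 fold change, a fold change, a mean log2 CPM, a mean CPM and a p-value for 17999 genes. 117 further rows of it held no values but for the CPM column. Per the file headers that table has no column of adjusted p-values, and the adjusted values cited from it were computed here. The ratio column of that table is the fold change on a linear scale as the authors deposited it.

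The count table was analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr at its default settings (a minimum count of 10 and a minimum total of 15), which left 15996 genes, and libraries were scaled by TMM. The quasi-likelihood F test (glmQLFit and glmQLFTest) compared the genotypes with no covariate, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were taken as the size of the log2 fold change divided by the square root of F, and 95% confidence intervals used the total degrees of freedom of each gene. CPM values use the TMM-scaled library sizes, and log2 CPM uses a prior count of 2. Single genes were also compared by an exact two-sided permutation test of log2 CPM over all 70 assignments, whose smallest possible p is 0.0286. Intervals cover the spread between these libraries. The labels do not say that the replicates of a genotype come from separate animals, so p-values measure the spread between these samples, which may be technical. No 2 libraries of a genotype matched within counting noise (chi-square per degree of freedom of 3.32 to 19.2 over genes), so none was taken as a repeat deposit of the same library, and each was counted once.

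Gene positions, lengths and GC contents were taken from GENCODE M21 on GRCm38, the build named by the submitters, and 15640 of the tested genes (97.8%) matched by name. The 29 gene lists (cell types of the hippocampus and its surroundings, synaptic genes, stress and immune responses, and housekeeping complexes), the genes to be named, the tests and most alternatives were chosen before the data were examined. A list was tested with camera of limma 3.58.1 against the other tested genes, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Repeats used an estimated correlation and the self-contained test fry. Genes within 1 Mb of Syt2 were examined as a group.

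The rule for naming genes took Syt2, Camk2a, Syt1 and Syt9 in every case. It also took up to 12 genes each way past the threshold whose libraries did not overlap between the genotypes, and, if fewer than 10 passed, the 10 genes next by unadjusted p, as values only. It added the members past the threshold of each described list or else the 2 with the smallest p, and up to 10 neighbours of Syt2. St6gal1 and the neighbours of St6gal2 were added after the values had been seen. For some lists, a gene that the rule names is not reported here.

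Alternatives were DESeq2 1.42.0, limma-voom, the likelihood ratio, exact and robust tests of edgeR, 3 other scalings, 2 other filters, a replicate block, 1 surrogate variable from sva 3.50.0, each library left out in turn, stricter thresholds, and windows of 0.5 and 5 Mb. A sex covariate was not fitted because every library had at most 3 counts of Xist and at least 1339 of Ddx3y, a Y-linked gene. The test of whether called genes cluster along the genome needed 10 called genes and was not run.

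The scripts were tested on simulated data. With the WT counts of 500 genes per fold size thinned in the real libraries (10 draws, 15996 genes), 37.6% of genes changed 1.25-fold, 67.4% of those changed 1.5-fold and 82.2% of those changed 2-fold were called. Among genes at a mean of at least 5 CPM these shares were 50.7%, 93.1% and 99.7%, and 2.45%, 60.9% and 92.6% passed the stricter limit that holds when a single gene differs. In 1 draw of counts from the library means with 200 changed genes, 94.3% of the 95% intervals of changed genes held the true value. Of 50 genes at each of 1.25-, 1.5-, 2- and 3-fold, 36%, 74%, 92% and 96% were called. Beside them, 13 unchanged genes were called. In a separate draw, camera called the 1 list that was shifted and 0 unrelated lists. Genes were drawn independently of each other, so that draw could not test lists whose genes vary together. In the real libraries the estimated correlation was 0.906 for the ribosomal protein genes.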

Results

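Poly(A) RNA of the hippocampus was sequenced in 4 WT libraries and 4 libraries of T29-1 Cre mice, all on a C57BL/6J background and 9 weeks old. T29-1 is a transgenic line in which Cre recombinase is expressed from the promoter of Camk2a, a kinase gene of forebrain excitatory neurons, and it is used to delete floxed genes in these cells. The title of the series names Syt2, so the comparison asks which transcripts, and Syt2 in particular, differ in mice that carry this transgene with no floxed target. The T29-1 Cre libraries held 26087006, 23358289, 27543742 and 27201990 counts in total and the WT libraries 26885740, 24741759, 30882631 and 23694841, for replicates 1 to 4 in each case. WT replicate 4 stood apart from the other 7 libraries on the first principal component of log2 CPM, which held 26.1% of the variance, with a score of -33.4 against -0.69 to 8.74.

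A single gene, St6gal2, differed between the genotypes past the threshold among 15996 genes tested. It rose in T29-1 Cre, and no gene fell. St6gal2 encodes a Golgi sialyltransferase that adds sialic acid in alpha-2,6 linkage to galactose residues of glycans. Its expression was 18.3 ± 2.15 CPM in WT (SD, n = 4) and 66.2 ± 12.3 CPM in T29-1 Cre (SD, n = 4), a 3.62-fold difference with a 95% confidence interval of 3.03 to 4.32. On the log2 scale the change was 1.85 (SE 0.119, edgeR quasi-likelihood adjusted p = 7.03e-06). All 4 T29-1 Cre libraries, at 68.8, 60.5, 82.1 and 53.4 CPM, lay above all 4 WT libraries, at 20.4, 19.6, 17.8 and 15.5 CPM, and the exact permutation test gave p = 0.0286, the smallest it can give. These values rest on 1407 to 2273 reads per T29-1 Cre library and 371 to 545 per WT library. The permutation p is no separate support, because St6gal2 was picked as the top gene of the same libraries. Libraries of the genotypes did not overlap for 289 genes (1.81%), where chance gives 2.86%.

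St6gal2 (ENSMUSG00000024172.10) is a protein-coding gene on the plus strand of chromosome 17, from 55445382 to 55514581 in GRCm38. No other gene of the count table that was matched by name to a position overlaps it. A second row with the same name held 0 counts. Its closest relative St6gal1 (chromosome 16, 23224740 to 23360350), chosen after the values were seen, was at 21.1 ± 1.27 CPM in WT and 21.7 ± 1.08 in T29-1 Cre (SD, n = 4 each), a log2 fold change of 0.04 (SE 0.0652, adjusted p = 0.998). In the authors' deposited table St6gal2 had a log2 fold change of 1.85, and it was also the 1 gene of 17999 with an adjusted p, computed here, under 0.05.

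**Figure D1:**
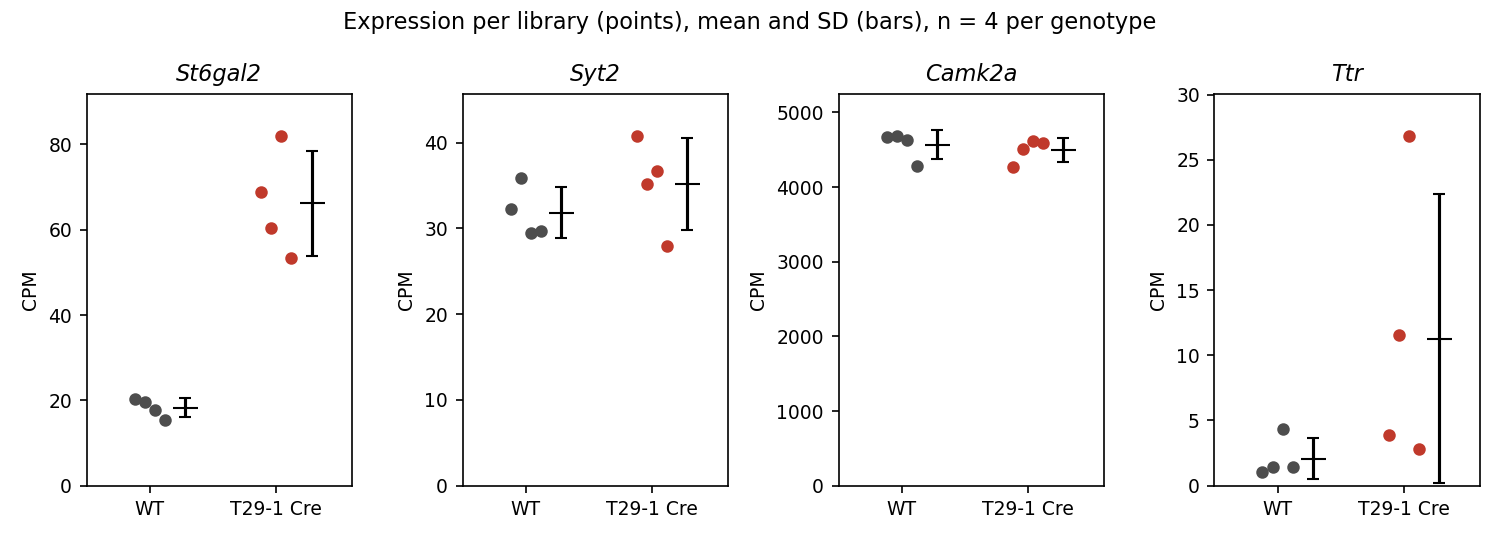
CPM (vertical axes, from 0) of St6gal2, Syt2, Camk2a and Ttr in each of the 4 WT and 4 T29-1 Cre libraries (points), with the mean and SD of each genotype (bars). The 4 T29-1 Cre libraries lie between 53.4 and 82.1 CPM for St6gal2, above the highest WT library at 20.4 CPM, whereas the genotypes overlap for the other genes shown.

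Syt2, which encodes a calcium sensor for fast vesicle release, did not differ beyond the spread between libraries. It was at 31.8 ± 2.96 CPM in WT and 35.2 ± 5.36 CPM in T29-1 Cre (SD, n = 4 each), a log2 fold change of 0.14 (SE 0.0989, adjusted p = 0.998). The T29-1 Cre libraries held 40.8, 35.2, 36.7 and 28.0 CPM and the WT libraries 32.3, 35.9, 29.5 and 29.8 CPM, and the exact permutation test gave p = 0.371. The 95% interval of the fold change ran from 0.954 to 1.28, so that a rise above 1.28-fold lies outside it. Leaving out T29-1 Cre replicate 1 or T29-1 Cre replicate 4 moved the log2 fold change to 0.06 or 0.24. Syt2 (ENSMUSG00000026452.15) lies on the plus strand of chromosome 1 from 134646677 to 134762593. Its end overlaps Ppp1r12b on the opposite strand, so that reads of the overlap are uncertain where counting ignored strand.

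The transgene promoter's own gene and the nearest relatives of Syt2 were likewise within the spread. Camk2a (chromosome 18, 60925618 to 60988152) was at 4567 ± 191 CPM in WT and 4493 ± 160 CPM in T29-1 Cre (SD, n = 4 each), with a log2 fold change of -0.02 and a 95% interval of -0.13 to 0.08. Syt1, the main synaptotagmin of forebrain synapses, had a log2 fold change of 0.07 (SE 0.0654) at 1419 ± 125 CPM in WT (SD, n = 4), and Syt9 one of 0.06 (SE 0.106) at 7.07 ± 0.92 CPM (SD, n = 4). Of 16 synaptotagmin genes tested, 9 had a higher and 7 a lower value, the median log2 fold change was 0.02, and those with the smallest p, Syt15 and Syt10, were at 0.46 (SE 0.252) and 0.29 (SE 0.188).

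The genes beside Syt2 were examined because a transgene can act on a stretch of chromosome. Of 30 tested genes within 1 Mb, edgeR called 0, and 0 had an unadjusted p under 0.05, as with DESeq2 and limma. Their median log2 fold change was 0.01, and the nearest 10 ran from Ppp1r12b (0.01, SE 0.0582) and Kdm5b (0.02, SE 0.0551) through Rabif, Klhl12, Ube2t, Adipor1, Cyb5r1, Tmem183a and Ppfia4 to Lgr6, which had the highest value (0.13, SE 0.148). Of 27 tested genes within 1 Mb of St6gal2, a region added after the values were seen, edgeR called 0 and DESeq2 and limma called 0, each with 1 gene at an unadjusted p under 0.05. All 27 lie beyond the end of St6gal2 and 0 before its start. The nearest, Pot1b at a distance of 137 kb, had a log2 fold change of -0.18 (SE 0.137), and the highest upper 95% limit of any of them was 1.13, below the lower limit of 1.598 for St6gal2.

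**Figure D2:**
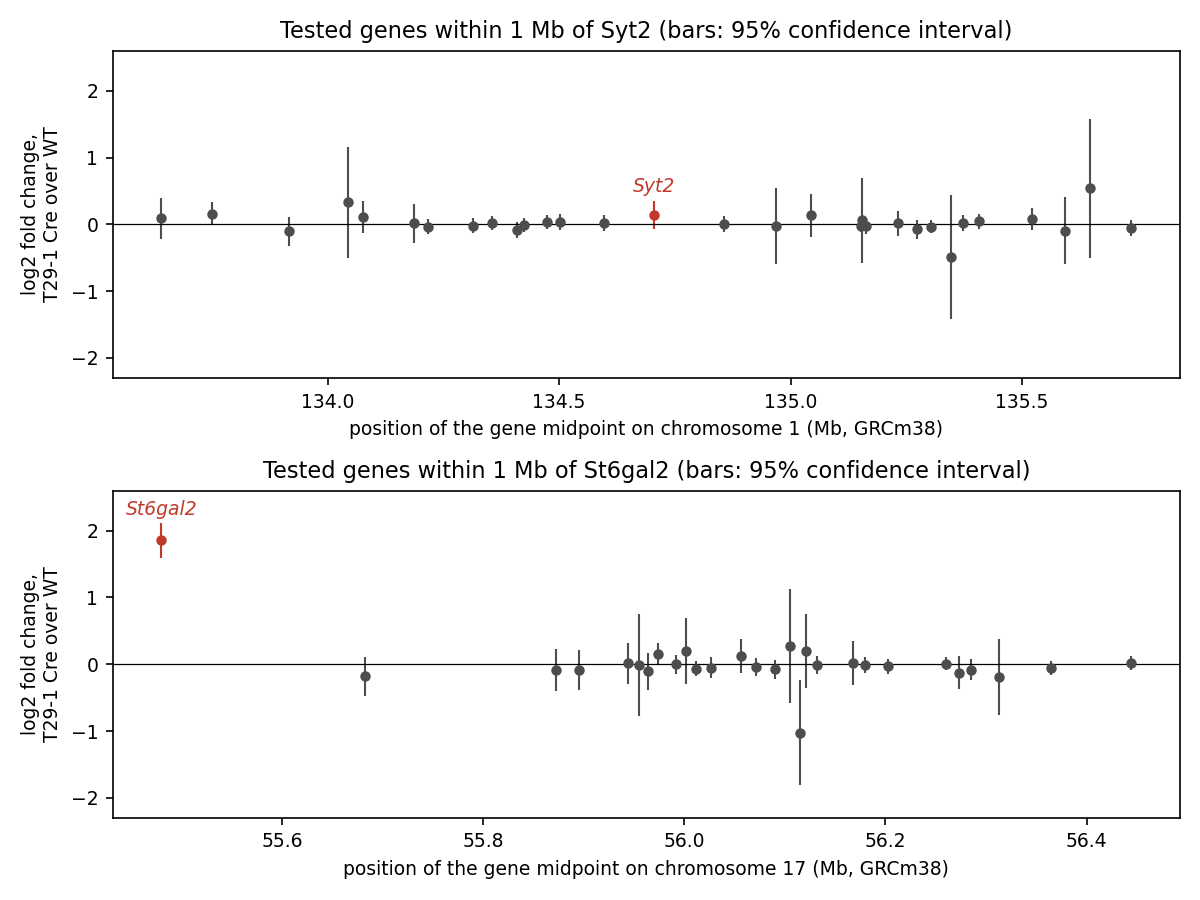
Log2 fold change of T29-1 Cre over WT (vertical axes) of each tested gene within 1 Mb of Syt2 (upper panel) and St6gal2 (lower panel), at the midpoint of the gene in Mb of GRCm38, with 95% confidence intervals (bars) and the named gene in red. St6gal2 stands at 1.85, while the medians of the neighbours are 0.01 around Syt2 and -0.03 around St6gal2.

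Beyond St6gal2, edgeR called 0 of 15995 genes, and the smallest adjusted p was 0.998. At an unadjusted p under 0.05 there were 388 genes (2.43%), St6gal2 included, where chance gives about 800. DESeq2 and limma-voom also called 0 beyond St6gal2, with 265 and 384 genes at an unadjusted p under 0.05. The 4 libraries of each genotype did not overlap for 289 genes (1.81%), where chance gives 2.86%. Among 11525 genes at a mean of at least 5 CPM, St6gal2 included, 11451 (99.4%) had a 95% interval within 1.5-fold in either direction. The interval reached 2-fold for 4 of the 11525, St6gal2 and Ttr among them. In simulated data smaller changes, and changes of genes at lower levels, were called less often, so that differences of these kinds are only partly covered.

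The 10 genes next by unadjusted p are given as values, each at an adjusted p of 0.998. Ttr, a thyroid hormone carrier made by the choroid plexus, was at 2.08 ± 1.54 CPM in WT and 11.3 ± 11.1 CPM in T29-1 Cre (SD, n = 4 each), a log2 fold change of 2.39 (SE 0.633), of which T29-1 Cre replicate 3 held 26.9 CPM. Without that library the value was 1.48, and without WT replicate 3 Ttr was at 3.10. With no filter on low counts, Ttr was called together with St6gal2 (log2 fold change 2.39, adjusted p = 0.000991). With the replicate number as a block, Ttr was called too (log2 fold change 2.30, adjusted p = 0.0144). The others were Sox18, a transcription factor of endothelial cells, at -0.39 (SE 0.101); Amn, a subunit of the vitamin B12 receptor, at 0.51 (SE 0.14); Lsm2, of the U6 snRNP, at -0.39 (SE 0.11); Grip2, a scaffold of AMPA receptors, at 0.23 (SE 0.065); and Rsph10b, of the radial spoke, at 0.46 (SE 0.134). Rsph10b overlaps Pms2 on its own strand, and Pcdhgb2, at 0.39 (SE 0.116), shares its region with other clustered protocadherins, so their reads are uncertain. The remaining 3 were low-expressed transcripts: Ccdc142os, antisense to Ccdc142, at -0.94 (SE 0.241), 4930579G24Rik, opposite to Etfdh, at -0.75 (SE 0.225), and the pseudogene Gm11585 at -0.73 (SE 0.213).

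**Figure D3:**
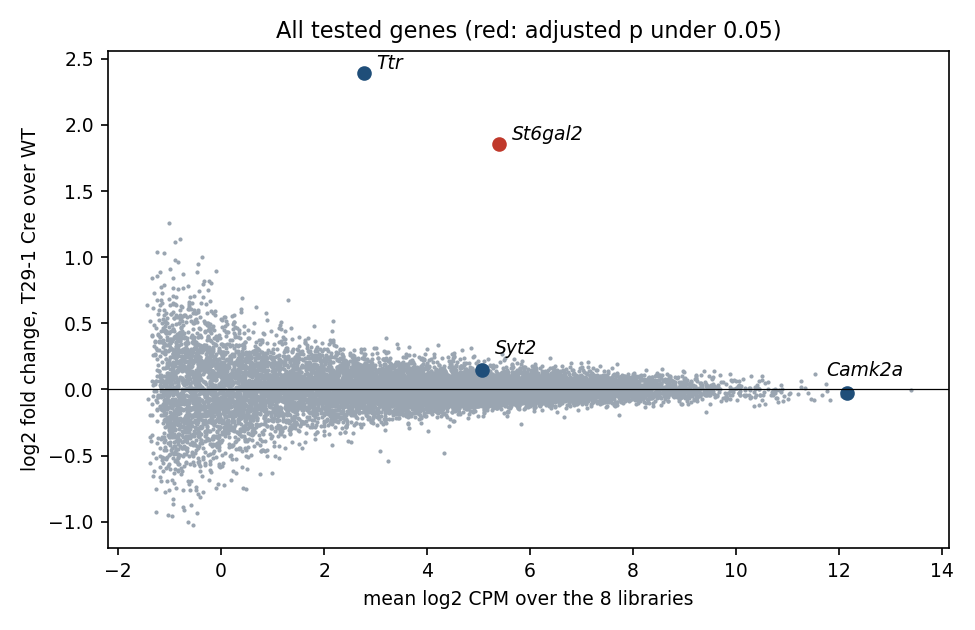
Log2 fold change of T29-1 Cre over WT (vertical axis) against mean log2 CPM over the 8 libraries (horizontal axis) for the 15996 tested genes. St6gal2 (red), at a log2 fold change of 1.85, is the 1 gene with an adjusted p under 0.05, and Ttr, at 2.39 with an SE of 0.633, did not pass.

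The 29 gene lists held 676 distinct tested genes, and edgeR called 0 of them over all genes, with 20 at an unadjusted p under 0.05 (DESeq2 0 and 17, limma 0 and 16). Adjusted over the list alone, 1 gene passed, Ttr in the choroid plexus list. Camera with the preset correlation placed 8 lists past its threshold, 6 lower and 2 higher in T29-1 Cre, each with a median change of a few percent except for the blood cell markers. With an estimated correlation it called 0 of the 29 lists and 0 were at an unadjusted p under 0.05, the adjusted p being 0.742 for each of the 8. Fry also called 0, with 0 at an unadjusted p under 0.05.

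The lists with the smallest p were ribosomal protein genes, chaperones and oxidative phosphorylation genes. Of 56 cytosolic ribosomal protein genes, 55 had a lower value in T29-1 Cre (median log2 fold change -0.08, adjusted p = 2.36e-08), among them Rplp2 at -0.15 (SE 0.0732) and Rps20 at -0.15 (SE 0.0747). Of 57 nuclear-encoded oxidative phosphorylation genes, 54 had a lower value (median -0.06, adjusted p = 2.13e-06), such as Ndufa2 at -0.17 (SE 0.0776) and Uqcrh at -0.13 (SE 0.0658). In WT replicate 4, the library that stood apart, the medians of these lists lay 0.27 and 0.22 above the mean of all libraries, and without it their adjusted p was 0.556 and 0.932. Of 27 genes of the unfolded protein response and chaperones, 26 had a lower value (median -0.10, adjusted p = 2.13e-06), with Dnajb11 at -0.17 (SE 0.0542) and Hspa5, the main chaperone of the endoplasmic reticulum, at -0.20 (SE 0.0655). In WT replicate 4 the median of this list lay 0.18 above the mean of all libraries, and without it the adjusted p was 0.00212. With an estimated correlation, the adjusted p of all 3 lists was 0.742.

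Among the cell types, all 20 oligodendrocyte markers had a lower value in T29-1 Cre (median -0.09, adjusted p = 0.00241), with Hapln2 at -0.14 (SE 0.0687). Their median in WT replicate 1 lay 0.26 above the mean of all libraries, and without that library the adjusted p was 0.607 (0.0538 without T29-1 Cre replicate 3). Of 20 dentate granule cell markers 15 had a lower value (median -0.05, adjusted p = 0.0266), with Maml2 at -0.21 (SE 0.0733) and Slc29a4 at -0.11 (SE 0.0578). All 5 tested blood cell markers had a lower value (median -0.30, adjusted p = 0.0498), with Hba-a1 at -0.32 (SE 0.146) and Hbb-bt at -0.64 (SE 0.299). Of 39 GABAergic interneuron markers 28 had a higher value (median 0.04, adjusted p = 0.0103), with Satb1 at 0.17 (SE 0.0648). Of 23 neocortical and subicular neuron markers 19 had a higher value (median 0.10, adjusted p = 0.0245), with Cux2 at 0.15 (SE 0.0701) and Whrn at 0.16 (SE 0.0749). Each of these 5 lists had an adjusted p of 0.742 with an estimated correlation. In WT replicate 1 the blood cell and ependymal markers lay above the mean of all libraries too, with medians of 0.702 and 0.705.

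These calls depended on single libraries and on the filter. With no filter on low counts the dentate granule cell, neocortical and subicular, and blood cell calls were lost (adjusted p = 0.0509, 0.0509 and 0.247). The dentate granule cell call was lost without T29-1 Cre replicate 1 (adjusted p = 0.0791) or T29-1 Cre replicate 4 (0.474), and without WT replicate 1 (0.109), WT replicate 2 (0.274) or WT replicate 3 (0.0908). The blood cell call was lost without T29-1 Cre replicates 2, 3 and 4 (adjusted p = 0.114, 0.114 and 0.215) and WT replicates 1 and 4 (0.607 and 0.132), in turn. The interneuron call was lost without T29-1 Cre replicate 4 (adjusted p = 0.215), WT replicate 1 (0.109) or WT replicate 2 (0.0504). The neocortical and subicular call was lost without T29-1 Cre replicates 1, 2 and 3 (adjusted p = 0.222, 0.0693 and 0.126) and WT replicates 1, 2 and 4 (0.109, 0.0504 and 0.104), in turn.

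The other 21 lists were not called. The synaptic lists had median log2 fold changes of 0.02 for 43 genes of presynaptic vesicle release (Rims2 0.17, Unc13c 0.28) and 0.04 for 39 postsynaptic glutamate receptors and scaffolds (Grin3a 0.13, Gria4 0.12). The medians of neuronal markers were -0.03 for excitatory principal neurons (Nrgn -0.12, Tbr1 0.13), 0.03 for CA1 and -0.02 for CA2 and CA3 pyramidal cells, 0.05 for thalamic, -0.01 for striatal and -0.02 for progenitor and immature neurons. Glial and vascular medians were -0.01 for astrocytes (Fgfr3 0.17, S100b -0.12), -0.05 for microglia and macrophages, 0.01 for oligodendrocyte precursors and 0.04 for endothelial and mural cells. Those of tissues around the hippocampus were 0.07 for the choroid plexus, 0.05 for meningeal fibroblasts and -0.17 for ependymal cells. The medians of stress and activity responses were 0.02 for DNA damage and p53 targets (Sesn1 -0.15, Phlda3 -0.15), -0.02 for interferon response genes (Ifi27 -0.10, Ifit2 0.15), 0.01 for immediate early genes (Bdnf -0.12, Dusp1 0.21) and -0.03 for reactive astrocyte and inflammation genes (C4b -0.20, Serpina3n -0.09). Mitochondrially encoded genes had a median of -0.04. Median, mean and camera differed in sign for the meningeal, astrocyte, striatal and progenitor lists.

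**Figure D4:**
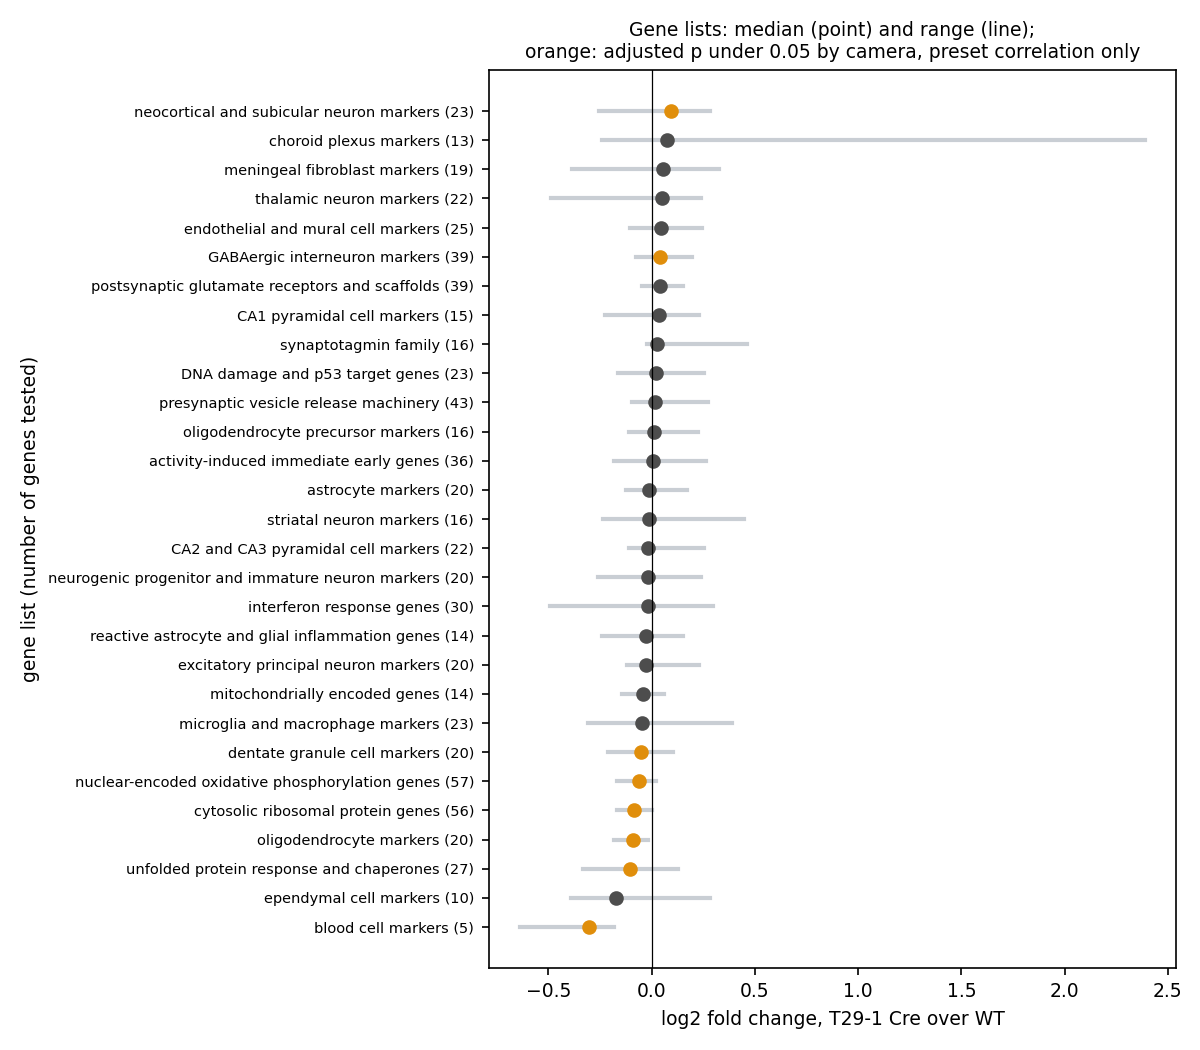
Median (points) and range (lines) of the log2 fold change of T29-1 Cre over WT (horizontal axis) for each of the 29 gene lists (vertical axis, with the number of genes tested). The 8 orange lists passed camera with the preset correlation alone, with medians between -0.30 and 0.10, and 0 passed with an estimated correlation.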

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

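In each genotype of 4 libraries, 28 measures were screened for a library far from the other 3 (15 genes, 8 lists and 5 measures of the whole library). 6 of the 56 groups held one, where chance gives about 1 in 20 for independent groups. These groups are not independent, and the 8 lists screened were those that camera had called, so the excess over chance was not tested. 4 of the 6 were in WT replicate 4: its score on the first principal component was -33.4 (the other WT libraries 2.41 to 8.74), its Camk2a level was 12.1 log2 CPM (12.2 in each of the others), and its median deviation from the mean of all libraries was 0.216 for oxidative phosphorylation genes (-0.0308 to -0.0181) and 0.27 for ribosomal protein genes (-0.044 to -0.00687). The Camk2a level of WT replicate 4, at 4283 CPM, was not the lowest of all libraries, as T29-1 Cre replicate 1 held 4264 CPM. In WT replicate 1 the oligodendrocyte markers lay 0.263 above the mean of all libraries (the other WT libraries -0.0598 to -0.00748). In T29-1 Cre replicate 3, Syt9 was at 2.78 log2 CPM (the others 2.93 to 2.95).

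The deviation of WT replicate 4 from the other WT libraries had a median size of 0.144 on the log2 scale among 11950 genes, against at most 0.0811 in any other library, and it followed properties of the transcripts. Across genes, which are not independent replicates, its Spearman correlation was 0.354 with GC content and -0.452 with transcript length, against -0.0813 to 0.0661 and -0.216 to 0.187 in the T29-1 Cre libraries. The other WT libraries, whose comparison includes WT replicate 4, reached -0.29 and 0.336. GC content and length are themselves correlated (-0.232), and each relation remained with the other held fixed (0.288 and -0.407), so a bias of this library towards short and GC-rich transcripts may account for its position. A different mixture of cell types stays open: the largest median deviation of 18 cell type lists was -0.488, for the ependymal markers, which lay at 0.929 in WT replicate 1, a library that did not stand apart on the first principal component. The design names no difference between WT libraries, so no biological explanation was tested.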

How the results depend on the processing

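St6gal2 was called in all 20 alternatives (log2 fold change 1.73 to 1.95, largest adjusted p 0.000681). These were planned for the count of genes called, and St6gal2 was followed in them only after it was seen. It was the only gene called in 18 of them and under both stricter thresholds. With no filter on low counts 2 genes were called, St6gal2 and Ttr, and the cause was not tested. Syt2 was called in none of its 20 alternatives (0.0644 to 0.240, smallest adjusted p 0.892). No neighbour of Syt2 or St6gal2 was called in any window or with any library left out. The other scalings moved the median of all genes by at most 0.0064 in size, as the value of -0.0064 for the upper quartile shows. Of 1775 values of named genes under alternatives, 26 changed sign, in 9 genes, none of them called.

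With the replicate number as a block, 2 genes were called, St6gal2 and Ttr (log2 fold change 2.30, adjusted p = 0.0144, against 0.000991 to 1 over the other alternatives for Ttr). No label says that the numbers pair the samples. The deviations of same-numbered libraries correlated at -0.0732, 0.0535, 0.0179 and -0.0345, and not every library correlated best with its own number. These values show no pairing, but they cannot exclude that a number marks a litter, day or batch.

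The 8 lists called by camera became 0 with an estimated correlation (smallest adjusted p 0.742), 0 with fry (0.715), which does not compare a list with other genes, and 0 with an estimated correlation and WT replicate 4 left out (0.967), a pair of choices made after seeing the data. With no filter on low counts 6 lists were called and 3 of the 8 calls were lost, those of the dentate granule cell, neocortical and subicular, and blood cell markers. The range over single libraries left out was 3 to 10 lists, with 4 without WT replicate 4, 3 without WT replicate 1 and 5 without WT replicate 2. Fewer libraries were tested in each, and the cause was otherwise not tested. In simulated data, changes were called less often over all genes than among those at a mean of at least 5 CPM.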

Other observations

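The tests of shared reads, of added cells and of the region around St6gal2, and the test for Ttr, were chosen only after the result was seen. St6gal2 was 47.9 CPM higher in T29-1 Cre, and 3 technical or tissue explanations were set against this. Reads drawn from St6gal1 would need a loss of that size, but St6gal1 held 21.1 CPM in WT, less than the gain. This comparison could therefore only come out against St6gal1 as the whole source. For a part of the gain, the 95% limit allows a loss of St6gal1 of at most 1.45 CPM. The second St6gal2 row held 0 counts. Added cells of a type that expresses St6gal2 would bring other transcripts up with it. Among 14291 other genes at a mean log2 CPM of at least 0, only Ttr had an interval that reached the lower limit of the St6gal2 change. Genes below that level were not counted, though Clic6, at a mean log2 CPM of -0.48, had an upper limit of 1.73 that reaches it too. Both are choroid plexus markers, so the count cannot exclude added cells whose markers are few or low. A change of the whole region is argued against by the median log2 fold change of -0.0307 of 27 neighbours, all beyond its end, with no tested gene before its start within 1 Mb. The insertion site of the transgene and the reads were not analysed here, and the cause of the St6gal2 change stays open.

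Ttr was at 2.81 to 26.9 CPM in the T29-1 Cre libraries and 1.08 to 4.37 CPM in the WT libraries. Choroid plexus tissue carried along in the dissection may account for this. Of the 22 genes of its list, 10 were at a mean of at least 1 CPM in these libraries, and 12 lower ones, 0 of them in another list, were summed as a measure of such tissue. Their sum, highest in T29-1 Cre replicate 3 at 7.15 CPM, followed Ttr over the 8 libraries with Spearman's rho of 0.619 (exact permutation p = 0.115) and Pearson's r of 0.89 (exact permutation p = 0.00466). Without the 2 farthest libraries, T29-1 Cre replicates 2 and 3, r was 0.357 and rho 0.0857, so for the sum the relation rests on them. Among the summed genes, Clic6, which the naming rule takes for its small p, was at 0.642, 0.860, 1.37 and 0.450 CPM in T29-1 Cre replicates 1 to 4. In WT replicates 1 to 4 it was at 0.262, 0.323, 0.751 and 0.418 CPM. Clic6 ordered the libraries as Ttr did, but for WT replicates 2 and 4, and its correlation with Ttr was not computed. With 8 libraries, carried-along tissue and a change of Ttr by genotype cannot be told apart.

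The count of genes called was larger in the real grouping than in any other: 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, called as many as 1 gene, and the highest of the others was 0. The real split is always counted, so 1 of 35 is the smallest share that this test can give. It rests on St6gal2 alone, so it repeats the exact permutation test of that gene and cannot by itself exclude chance. The gene lists behaved otherwise. As many as 8 lists passed camera with the preset correlation in 18 of the 35 splits, the highest of the others being 13, so chance cannot be excluded for the number of lists called. At an unadjusted p under 0.05 the real split had 388 genes and the others 275 to 1611, which points to differences between libraries other than genotype.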
